A study of Mus musculus with 6 samples.

How the data were processed

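RNA from endothelial cells of mouse skin was measured on 6 one-colour Agilent expression arrays, 3 with wild-type samples and 3 with samples lacking APJ, the apelin receptor encoded by Aplnr. Per the labels, each sample carries the number of 1 mouse, the strain is C57Bl/6J throughout, and the cells were isolated by fluorescence-activated sorting. Xist and the Y-linked genes Ddx3y and Eif2s3y were well above background on every array, while the Y-linked gene Kdm5d was on 0 of 6. The number of animals behind each sample is therefore treated as unknown. Per the labels' protocols, RNA was prepared on RNeasy columns and 0.1 µg was labelled with the dye Cy3. The group of each array came from its genotype label and the replicate number from its title. The names of the deposited scanner files carry an embryonic stage, which no label used here states, and the labels used here give no surface markers of the sort.

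The deposited scanner files hold a fluorescence intensity for each spot on a linear scale, written by Agilent Feature Extraction 10.7.3.1 per the file headers. The processed intensity used here is that software's background-subtracted and detrended Cy3 value, per the file headers, and it had not been normalised between arrays. The authors' deposited value table holds the same intensity multiplied by 1 constant per array, between 2.29 and 3.69, within a relative deviation of 5e-10. Its column medians were 63.46, 62.09 and 65.15 for wild type replicates 1 to 3 and 66.98, 60.3 and 63.25 for APJ knockout replicates 1 to 3. The table was therefore linear and not centred by gene, and what set the constants is not given in the sources used here.

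Each array carried 59305 spots that were not controls, from 55681 probes. No spot was saturated, and between 126 and 179 spots per array, marked by the scanner software as outliers, were left out. Processed intensities were taken to log2, and the array's 75th percentile of log2 intensity was subtracted. Spots of 1 probe were averaged. A probe was tested if it was well above background, by the software's own call, on every array of at least 1 group. Each gene symbol was represented by its probe with the highest mean signal over all 6 arrays, and a probe without a symbol was tested on its own. This left 24235 genes and unnamed probes, 13457 of them with a symbol.

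Symbols came from a table of RefSeq genes matched by accession without version. Of 27016 probes with a curated RefSeq accession, 97.7% received a symbol, and over all probes 47.4% did, giving 20018 symbols. Probes for predicted transcripts, Ensembl transcripts and genome intervals stayed mostly unnamed. The reference table follows a later mouse assembly than the coordinates on the array, so it was used for names, chromosome numbers and the order of neighbouring genes only, and no coordinate is given.

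Differences were fitted with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with genotype as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over everything tested, with a threshold of 0.05. Every log2 difference is APJ knockout minus wild type, with the standard error (SE) of the fit, and group means carry the standard deviation (SD) of 3 arrays. A gene that was not well above background on any array of 1 group has only a bound there. For such a gene the ratio is given as at least N-fold, against the mean over that group's arrays of the higher of the probe's own signal and the lowest signal called well above background. For Kif9, Hal, Fam155a and Sfrp1 this equals the fitted ratio. It leaves out the spread between arrays, so a smaller true ratio is possible. Gene lists were fixed before the data were examined, as were the main test, the rule for named genes and all alternatives except those described here as added. Of 33 lists, 32 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation, the directional fry test and a rank form of camera were alternatives. Exact permutation tests and Fisher's exact tests were two-sided.

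The rule for named genes took, in each direction, the 12 named genes with the largest log2 difference among those past the threshold whose knockout arrays all lay on 1 side of the wild-type arrays. Symbols that are only clone or prediction names were passed over. Aplnr, Apln and Sfrp1 were added as genes known from the study, and up to 4 members of each list with the smallest unadjusted p were added. The values of 3 genes that the rule takes are not reported here, although counts and list tests include them. Other genes are said to have been chosen after their values were seen. Among called genes with more than 1 tested probe, all 25 had every probe moving the same way, and 4 (Clic4, Gcnt1, Pla2g5 and Stmn1) had a probe that moved by less than 50% of the value used.

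The arrays came from 2 slides, which were also 2 scanning batches. Slide 1 held replicates 1 and 2 of both groups and slide 2 held replicate 3 of both. The first principal component, with 39.4% of the variance, parted the slides, and the second, with 29.6%, parted the genotypes. The share of an array's replicate number in its signal was checked from deviations around the group means. Same-numbered arrays correlated at 0.226, 0.152 and 0.646, all above the 0.1 set for treating numbers as pairs. The main fit, fixed beforehand, was nevertheless kept without a block. It called 134 genes or unnamed probes, against 5 with the replicate number as a block. The pairing followed the shared slide: arrays of replicates 1 and 2 with different numbers correlated as well (0.28 and 0.357). Arrays on different slides correlated between -0.473 and -0.349. Because slide 2 held only replicate 3, the slide cannot be told apart from anything else that replicate 3 of both groups shared. Fits with the slide as a block and with the replicate number as a block were both run, and slide values are given within each slide, although slide 2 held only 1 array per group.

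The alternatives were quantile normalisation, median scaling, the authors' deposited table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, every probe on its own, an intensity trend with and without robust fitting, array weights, both blocks, other thresholds, other set tests and each array left out in turn. A normexp background correction planned on mean spot signals was run on median spot signals instead, because mean spot signals were not used here, and it counts as added after seeing the data, as does a fit to the arrays of slide 1 alone. The steps were tested on simulated data for the same comparison, with 200 of 24235 genes changed and the slide effect of these arrays included. Without a block the fit recovered 2%, 66%, 90% and 98% of genes changed by log2 0.5, 1, 2 and 3, with 50 genes of each size, and 1 of its 129 calls was an unchanged gene. The simulated noise came from the fit without a block, which already held the slide's spread, so that spread entered 2 times. With the slide as a block 7 of 143 calls were unchanged genes. Without the added slide effect and without a block 8 of 148 were, and 6% of genes changed by log2 0.5 were recovered. Changes near log2 0.5 in single genes were therefore mostly below what 3 arrays per group detect. All 3 lists shifted by log2 0.3 passed the set test, and none of the other simulated lists did. The simulated genes varied independently, whereas the estimated correlation within real lists reached 0.67, for keratinocyte markers. The simulation therefore does not test the preset correlation of 0.01 for lists whose members vary together. Python 3.11.15 with matplotlib 3.10.9 drew the figures.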

Results

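Gene expression was measured in endothelial cells sorted from mouse skin, in 3 wild-type samples and 3 samples lacking APJ, the receptor for the peptide apelin. The names of the scanner files, but no label, give an embryonic stage. The comparison asked which genes of these cells differ when the receptor is absent. Between 50.36% and 58.01% of the 55681 probes were well above background on each array, and the 75th percentile of intensity lay between 251.8 and 399.7. Expression levels are log2 signals relative to that percentile of the same array. Arrays of different genotype on the same slide correlated at 0.9913 to 0.9949, and those of the same genotype on different slides at 0.9913 to 0.9921. The number of animals behind each sample is unknown, so the p-values measure only the spread between these 6 samples, and the number of arrays limits the precision of each value.

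Aplnr, the gene for APJ on chromosome 2 (probe accession NM_011784), fell in the knockout cells to 30.9% of its wild-type level. Its log2 signal was 3.65 ± 0.26 in wild type and 1.95 ± 0.28 in the knockout (SD, n = 3 each), a difference of -1.69 ± 0.19 (SE, limma adjusted p = 0.0237). The wild-type arrays read 3.35, 3.77 and 3.82 and the knockout arrays 1.89, 1.71 and 2.26, so every array matched its label. Apln, which encodes the ligand apelin and marks sprouting endothelium, read 5.10 ± 0.12 in wild type and 5.34 ± 0.16 in the knockout (SD, n = 3 each). Its difference of 0.24 did not pass the test (limma adjusted p = 0.775), and Apln and Aplnr were the only tested members of the list of apelin receptor and ligands, too few for a list test. The Aplnr signal remained well above background in all knockout arrays, and because it came from 1 probe whose position against the deleted part of the gene is unknown here, it checks the labels only in part. An exact permutation test gave p = 0.1 for Aplnr, the smallest that 3 arrays against 3 allow, and p = 0.2 for Apln. The difference in Aplnr was -1.76 within slide 1 and -1.57 within slide 2. Its adjusted p was 0.0153 with the slide as a block and 0.0791 with the replicate number as a block, and leaving out any 1 array except APJ knockout replicate 3 ended the call (0.0507 to 0.148).

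Across the transcriptome 89 genes or unnamed probes rose and 45 fell in APJ-deficient cells, in the fit without a block. The larger increases among named genes included Serpina3f, a serine protease inhibitor, and Inhbb, the βB subunit of activins and inhibins. Serpina3f rose by 3.28 ± 0.18 on the log2 scale (SE, n = 3 per group) and Inhbb by 2.58 ± 0.27. Kif9, a kinesin motor protein, was at least 9.42-fold higher, and Loxl4, a lysyl oxidase that cross-links matrix, at least 7.51-fold higher, both being not well above background in wild type. Lrrc55, an auxiliary subunit of potassium channels, fell (-3.92 ± 0.39), a size that is imprecise because only 1 of 3 knockout arrays was well above background. Fam155a, a partner of the sodium leak channel, was at least 4.92-fold lower and not well above background in the knockout. Ratios given as at least a value leave out the spread between arrays.

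Lrmda, which acts in melanocyte differentiation, rose by 2.89 in the knockout, 1 wild-type array being not well above background, and Fam205a2 by 2.51. Gbp3, a guanylate-binding protein induced by interferon, rose by 2.22 ± 0.23, whereas its neighbour Gbp7 fell, with a difference of -1.61 ± 0.18 (SE, n = 3 per group). Hal, the histidine-degrading ammonia lyase, was at least 4.23-fold higher and not well above background in wild type. The zinc finger gene Zfp69 rose by 1.91, Cuedc1 by 1.81, the asparaginase gene Aspg by 1.69 and the serine carboxypeptidase gene Scpep1 by 1.63.

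Madcam1, an endothelial addressin that binds lymphocyte integrin, fell from 5.57 ± 0.09 to 3.83 ± 0.17 (SD, n = 3 each), a difference of -1.74. Gcnt1, which builds the branched glycans that selectins bind, fell (-1.62), although another of its probes moved by less than 50% of that value. Kank1, an adaptor at cell adhesions (-1.92), the TRIM family gene Trim12a (-2.01) and the nuclear protein gene Trnp1 (-1.39) also fell. Hes5, a transcriptional repressor induced by Notch, fell with a difference of -1.23 ± 0.16 (SE, n = 3 per group), and Dusp26, a phosphatase, with one of -1.20 ± 0.12.

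The 24 genes that the naming rule took by size, 12 in each direction and Aplnr among them, had limma adjusted p between 0.00443 and 0.04. A530016L24Rik, passed over for its clone name and chosen here after its value was seen, rose by 3.94 (limma adjusted p = 0.00167). It also passed with the replicate number as a block (adjusted p = 0.0326). Of the 134 calls, 49 rising and 28 falling carried a gene symbol and 57 were unnamed probes. All 134 calls had knockout and wild-type arrays that did not overlap, which passing the threshold with 3 arrays per group nearly requires. Over everything tested 12.2% did not overlap, against 10% by chance. Of the calls, 95 differed by at least 2-fold. Of the 24 genes taken by the rule, 8 lay in chromosome segments where at least 3 called genes gathered, among them Serpina3f, Aspg, Cuedc1, Scpep1, Gcnt1, Kank1 and Trnp1. Segments of 2 called genes held Gbp3 with Gbp7, Fam205a2 with Gm3893, and Aplnr with Lrrc55. Lrrc55 is the next protein-coding neighbour of Aplnr. With the slide as a block 184 rose and 101 fell, and 23 of the 24 named genes passed, Gcnt1 having an adjusted p of 0.0515. With the replicate number as a block 4 rose and 1 fell, and of the 24 only Fam155a passed (adjusted p = 0.0407, against up to 0.101 for the others). Leaving out 1 array at a time left 11 to 45 higher and 1 to 26 lower, with 4 to 15 of the 24 named genes past the threshold.

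**Figure D1:**
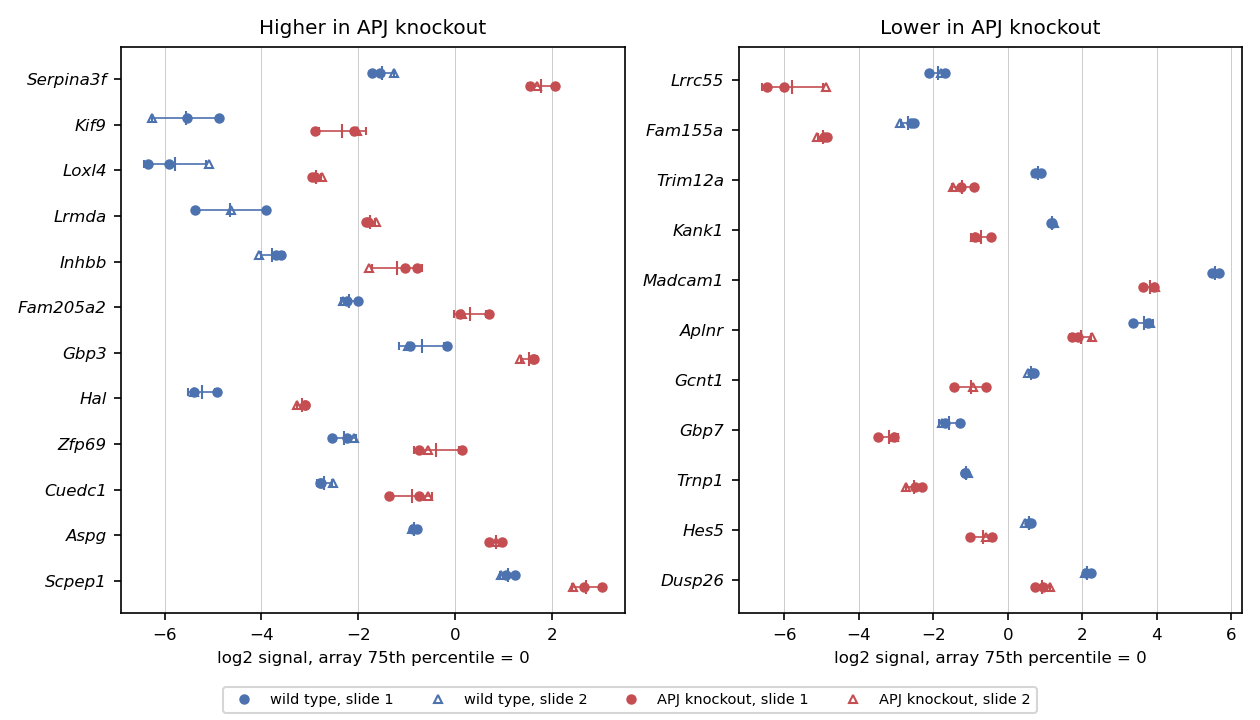
Log2 signal of 23 of the 24 genes that the naming rule took by size, relative to each array's 75th percentile, for each array (circles, slide 1; triangles, slide 2), with vertical ticks at group means and bars of 1 SD (n = 3 per group). Blue marks wild type and red APJ knockout, and the groups did not overlap for any gene shown, as the naming rule required. Aplnr lay between 3.35 and 3.82 in wild type and between 1.71 and 2.26 in the knockout.

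Genes of the hypoxia response, which encode glycolytic enzymes and secreted angiogenic factors, rose by camera with a preset correlation but not with an estimated one. Of 21 tested members 20 were above 0, with a median log2 difference of 0.30 (camera adjusted p = 7.85e-14, lost at 0.069 with an estimated correlation; fry 0.0134). No member passed over all genes, and 9 rose when adjusted over the list alone. With the slide as a block Adm passed (adjusted p = 0.0232). Adm, the vasodilator peptide adrenomedullin, differed by 1.12 ± 0.17 (SE, n = 3 per group, limma adjusted p = 0.0585), P4ha2, a collagen prolyl hydroxylase, by 0.68 ± 0.13, and the glycolytic regulators Pfkfb3 and Pfkfb4 by 0.44 and 0.48. The median was 0.36 within slide 1 and 0.20 within slide 2.

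Tip cell and sprouting genes, which mark the leading cells of growing vessels, rose under the same limit. The median difference was 0.24, with 20 of 21 members above 0 (camera adjusted p = 7.48e-13, lost at 0.155 with an estimated correlation; fry 0.0262). Kcne3, a potassium channel subunit, rose by 1.42 ± 0.11 and Ramp3, a co-receptor for adrenomedullin, by 1.20 ± 0.10 (SE, n = 3 per group, limma adjusted p = 0.0122 and 0.0142), but neither passed with the replicate number as a block (0.0791 and 0.074). Esm1, a secreted proteoglycan of tip cells, differed by 1.09 without passing (adjusted p = 0.0529). With the slide as a block 4 members of the list passed over all genes, against 2 without it. Adjusted over the list alone, 8 members rose, and 16 of the 21, Adm included, are also held by another list. The median was 0.26 within slide 1 and 0.22 within slide 2.

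Lymphatic endothelial markers had the largest median difference of the lists that rose. It was 0.49 over 14 members, 13 of them above 0 (camera adjusted p = 1.22e-11), and the call was lost with an estimated correlation (adjusted p = 0.069; fry 0.0262). The median was 0.53 within slide 1 and 0.40 within slide 2. No member passed over all genes, 2 did with the slide as a block, and 10 rose when adjusted over the list alone. Stab2, a scavenger receptor for hyaluronan, differed by 0.71 ± 0.14, Flt4, the receptor for VEGF-C, by 0.38 ± 0.08, Mmrn1, a multimerin, by 0.48 ± 0.11, and Pdpn, the glycoprotein podoplanin, by 0.49 ± 0.11 (SE, n = 3 per group). Macrophage markers moved in the same direction: their median was 0.45, with 14 of 15 members above 0 and 6 that rose when adjusted over the list alone (camera adjusted p = 1.34e-06). That call was lost with an estimated correlation (adjusted p = 0.425), and fry did not pass (0.316). Lyz2, a lysozyme, differed by 1.83 ± 0.30, the complement genes C1qa and C1qc by 1.79 ± 0.35 and 1.91 ± 0.45, and Aif1, a calcium-binding protein of macrophages, by 1.11 ± 0.29 (SE, n = 3 per group). In wild type, Lyz2 was well above background on 1 of 3 arrays and C1qa and C1qc on 2 of 3, so these sizes are imprecise. The macrophage median was 0.46 within slide 1 and 0.26 within slide 2. Without wild type replicate 2 the macrophage median was 0.26 and without wild type replicate 3 it was 0.96. C1qa passed over all genes only with the replicate number as a block (adjusted p = 0.0431 against 0.123 without it).

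Genes of the TGF-β and BMP response rose with a median of 0.11 and a mean of 0.25, 15 of 19 members being above 0 (camera adjusted p = 2.23e-05), and the call was lost with an estimated correlation (0.0781; fry 0.0334). Tgfbi, a matrix protein induced by TGF-β, rose by 0.80 ± 0.09 (SE, n = 3 per group, limma adjusted p = 0.0237, but 0.074 with the replicate number as a block), and 4 members rose when adjusted over the list alone. The inhibitory Smads Smad6 and Smad7 differed by 0.50 ± 0.13 and 0.47 ± 0.12. The median was 0.05 within slide 1, 0.23 within slide 2 and 0.19 without wild type replicate 1.

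Fatty acid and lipid uptake genes rose with a median of 0.17, 11 of 16 members being above 0 and none passing, over all genes or adjusted over the list alone (camera adjusted p = 0.00389). The call was lost with an estimated correlation (adjusted p = 0.685), and fry did not pass (0.316). Vldlr, a receptor for lipoproteins, differed by 0.44 ± 0.10, and Fabp4, a fatty acid carrier of capillaries, by 0.63 ± 0.26 (SE, n = 3 per group). The median was 0.16 within slide 1, 0.08 within slide 2, 0.07 without wild type replicate 1 and 0.27 without wild type replicate 3. Platelet and megakaryocyte markers rose with a median of 0.19, 8 of 11 being above 0 (camera adjusted p = 0.00458). That call was lost with an estimated correlation (0.425), with the replicate number as a block (0.0836) and without APJ knockout replicate 1 (0.0548), and fry did not pass (0.178). Clec1b, the platelet receptor for podoplanin, differed by 0.70 ± 0.11, and it, Ppbp (0.76) and Pf4 (0.48), both platelet chemokines, rose when adjusted over the list alone. The platelet median was 0.13 within slide 1, 0.21 within slide 2 and 0.13 without wild type replicate 1. With the slide as a block 1 platelet marker passed over all genes.

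Keratinocyte markers fell in the knockout with a median of -1.14, 13 of 14 being below 0 and none passing, over all genes or adjusted over the list alone (camera adjusted p = 0.00458). The call was lost with an estimated correlation (adjusted p = 0.685) and with the replicate number as a block (0.0752), and fry did not pass (0.649). Krt14, a keratin of basal epidermis, differed by -1.31 ± 0.70, Krt10, a keratin of upper epidermis, by -1.05 ± 0.58, and the epidermal adaptor Sfn by -0.85 ± 0.23 (SE, n = 3 per group). The median was -0.13 within slide 1 and -2.67 within slide 2, and without wild type replicate 3 it was -0.32 (camera adjusted p = 0.719), without APJ knockout replicate 3 it was -0.89 (0.0725), and without wild type replicate 1 it was -2.02 (1.78e-09).

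General endothelial identity genes did not pass: the median over 24 pan-endothelial members was 0.03 (camera adjusted p = 0.361), with Flt1, a VEGF receptor, at 0.26 ± 0.08 and Eng, a TGF-β co-receptor, at 0.27 ± 0.11 (SE, n = 3 per group). Arterial markers had a median of 0.02 and a mean of -0.02 (adjusted p = 0.943), with the chemokine Cxcl12 at -0.61 and its receptor Cxcr4 at 0.49. Venous markers had a median of 0.02, a mean of -0.04 and an upward test (adjusted p = 0.843), and adjusted over the list alone 2 rose and 1 fell. Shear stress genes had a median of 0.18 (adjusted p = 0.061, and 0.0472 with the slide as a block), and 0.10 within slide 1 and 0.11 within slide 2. With 1 array left out that median lay between 0.09 without wild type replicate 3 and 0.26 without APJ knockout replicate 3, and the adjusted p between 0.00939 and 0.394, passing in 3 of the 6 fits. Among them Angpt2, an antagonist of the Tie2 receptor, differed by 0.87 ± 0.14, and Aqp1, a water channel, by 0.87 ± 0.16, and adjusted over the list alone 2 members rose and 1 fell. The Notch pathway list did not pass (median -0.02, adjusted p = 0.451), and Hes5 was its only member past the threshold.

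Sfrp1, a secreted inhibitor of Wnt signalling, was at least 6.29-fold lower in the knockout but did not pass (limma adjusted p = 0.055). Its log2 signal was -2.95 ± 0.40 in wild type and -5.60 ± 0.76 in the knockout (SD, n = 3 each), where no array was well above background. The fitted difference was -2.65 ± 0.39 (SE, n = 3 per group), with -3.19 within slide 1 and -1.57 within slide 2, so the ratio is imprecise. The exact permutation p for Sfrp1 was 0.1, the smallest possible. Secreted Wnt modulators as a list had a median of 0.04, a mean of -0.22 and an upward test (adjusted p = 0.855). Wnt/β-catenin targets had a median of 0.00265, a mean of -0.02 and a downward test (adjusted p = 0.855). Adjusted over the list alone, 1 secreted modulator, the Dickkopf family member Dkk3, rose and Sfrp1 fell, and among the targets the receptor gene Tnfrsf19 fell.

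Matrix genes did not pass as groups. Proteases and their inhibitors had a median of -0.06, a mean of 0.08 and an upward test (camera adjusted p = 0.464), and adjusted over the list alone 3 rose and 1, the gelatinase gene Mmp2 (-0.54), fell. Basement membrane genes had a median of 0.03 (adjusted p = 0.697). Fn1, which encodes fibronectin, differed by 0.69 ± 0.11 (SE, n = 3 per group, limma adjusted p = 0.0685) and rose when adjusted over the list alone. It passed with the slide as a block (limma adjusted p = 0.0196). Guidance and junction genes had a median of 0.03 (adjusted p = 0.0967, but a median of 0.09 and 0.0198 without APJ knockout replicate 3), 3 of them rising when adjusted over the list alone, with the semaphorin Sema3f at 0.96 and the guidance ligand Slit2 at 0.61. Sema3f passed over all genes only with the slide as a block (limma adjusted p = 0.048, against 0.0818 without a block). Chemokines and leukocyte adhesion genes had a median of -0.11 (adjusted p = 0.0967). With 1 array left out it ran from -0.16 without APJ knockout replicate 2 (0.00164) to 0.01 without APJ knockout replicate 1 (0.725), and the list also passed without wild type replicate 2 (0.0232). Madcam1 was the only member of that list past the threshold, while Cxcl12 passed as well with the slide as a block (limma adjusted p = 0.0323). FGF, ERK and AKT signalling genes had a median of 0.17 (adjusted p = 0.25; 0.05 without wild type replicate 3), the cell cycle list -0.00226 (adjusted p = 0.821, its test upward and its mean 0.02), the interferon response -0.005 (adjusted p = 0.654, but a median of 0.28 and 0.0153 without wild type replicate 1), and immediate early genes 0.11 with a mean of -0.01 (adjusted p = 0.843). The immediate early median ran from -0.14 without APJ knockout replicate 2 to 0.20 without wild type replicate 1, without passing.

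Markers of other cell types that a skin sort could hold gave no further call over all 6 arrays, although several depended on 1 array. Medians were -0.04 for dermal fibroblasts (camera adjusted p = 0.888), -0.15 for mural cells (0.843), 0.33 for neutrophils (0.451), 0.09 for erythroid cells (0.238, with the embryonic globin Hbb-y at a log2 signal of 6.00 in wild type and 6.19 in the knockout), -0.10 for Schwann cells and neurons (0.487), 0.02 for melanoblasts (0.855), -0.08 for skeletal muscle (0.821), and -0.03 for mast cells, whose mean was 0.08 (0.895). With 1 array left out, dermal fibroblast markers ran from -0.34 without APJ knockout replicate 1, which passed (0.00584), to 0.27 without APJ knockout replicate 2, and erythroid markers from -0.095 without APJ knockout replicate 1 to 0.34 without wild type replicate 2, which passed (0.00259). Neutrophil markers ran from 0.08 to 0.61 and mast cell markers from -0.28 to 0.62 without passing, and neutrophil markers passed fry with the slide as a block (adjusted p = 0.0239). Mural cell markers ran from -0.29 without wild type replicate 1 to 0.00345 without wild type replicate 2, also without passing. Sex-linked genes had a median of -0.05 (adjusted p = 0.487). Xist, expressed from the inactive X chromosome, and the Y-linked genes Ddx3y and Eif2s3y were well above background on all 6 arrays.

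**Figure D2:**
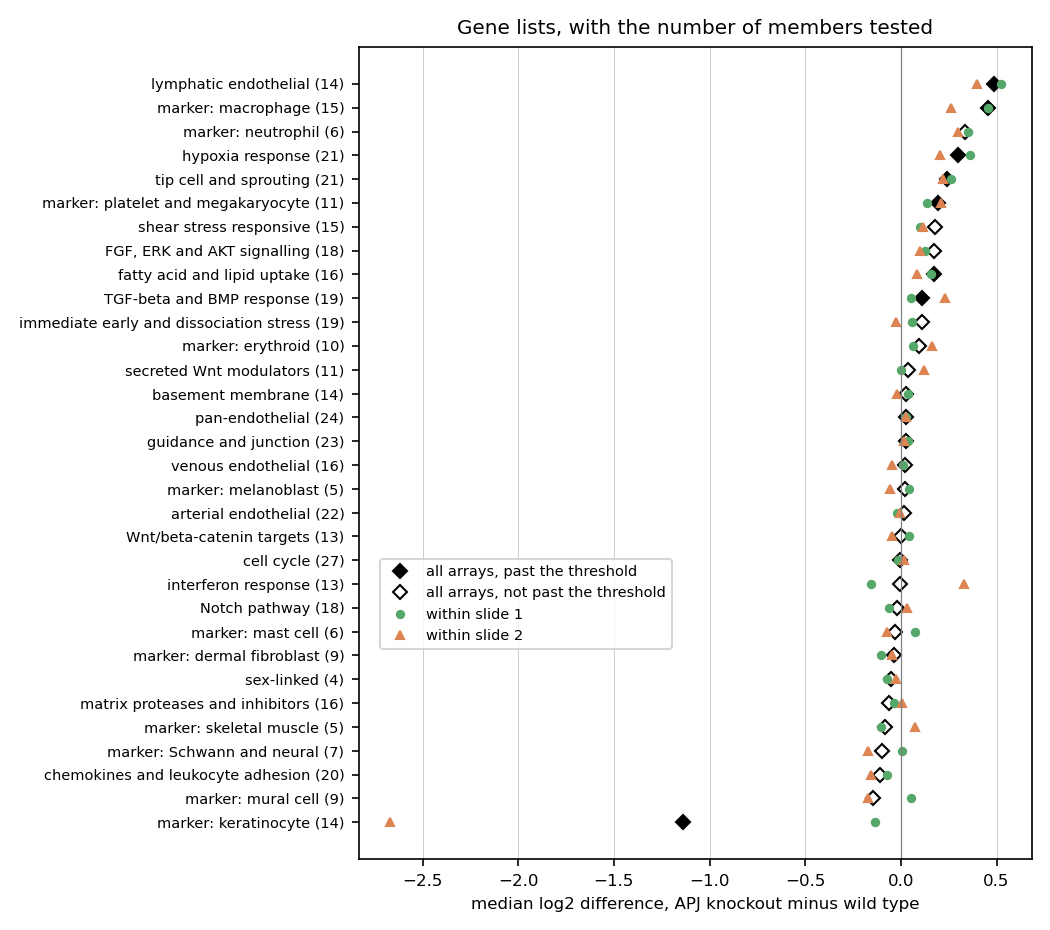
Median log2 difference, APJ knockout minus wild type, of each tested gene list over all 6 arrays (diamonds, filled where the camera adjusted p passed 0.05), within slide 1 (circles) and within slide 2 (triangles), with the number of tested members in parentheses. Lymphatic markers had the highest median, 0.49, and keratinocyte markers the lowest, -1.14, which was -0.13 within slide 1.

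Genes around Aplnr were examined because a targeted allele can carry sequence from another strain. On chromosome 2, which holds Aplnr, 3 of 1062 tested named genes other than Aplnr were called, against 73 of 12394 elsewhere (Fisher's exact p = 0.283). They were Lrrc55, the sodium channel gene Scn3a (1.45) and the transcription factor gene Pax1 (1.32), the last 2 chosen after their values were seen, and none of the 3 passed with the replicate number as a block (adjusted p = 0.0863 to 0.121). Pax1 was well above background on 2 of 3 wild-type arrays. Within 20 Mb of Aplnr 2 of 179 were called, against 1 of 883 on the rest of the chromosome (odds ratio 9.93, Fisher's exact p = 0.0754). Scn3a lay near the edge of that window: within 10 Mb only Lrrc55 was called (odds ratio 4.48, Fisher's exact p = 0.273), and within 5 Mb again 1 of 39 (odds ratio 13.3, Fisher's exact p = 0.106).

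**Figure D3:**
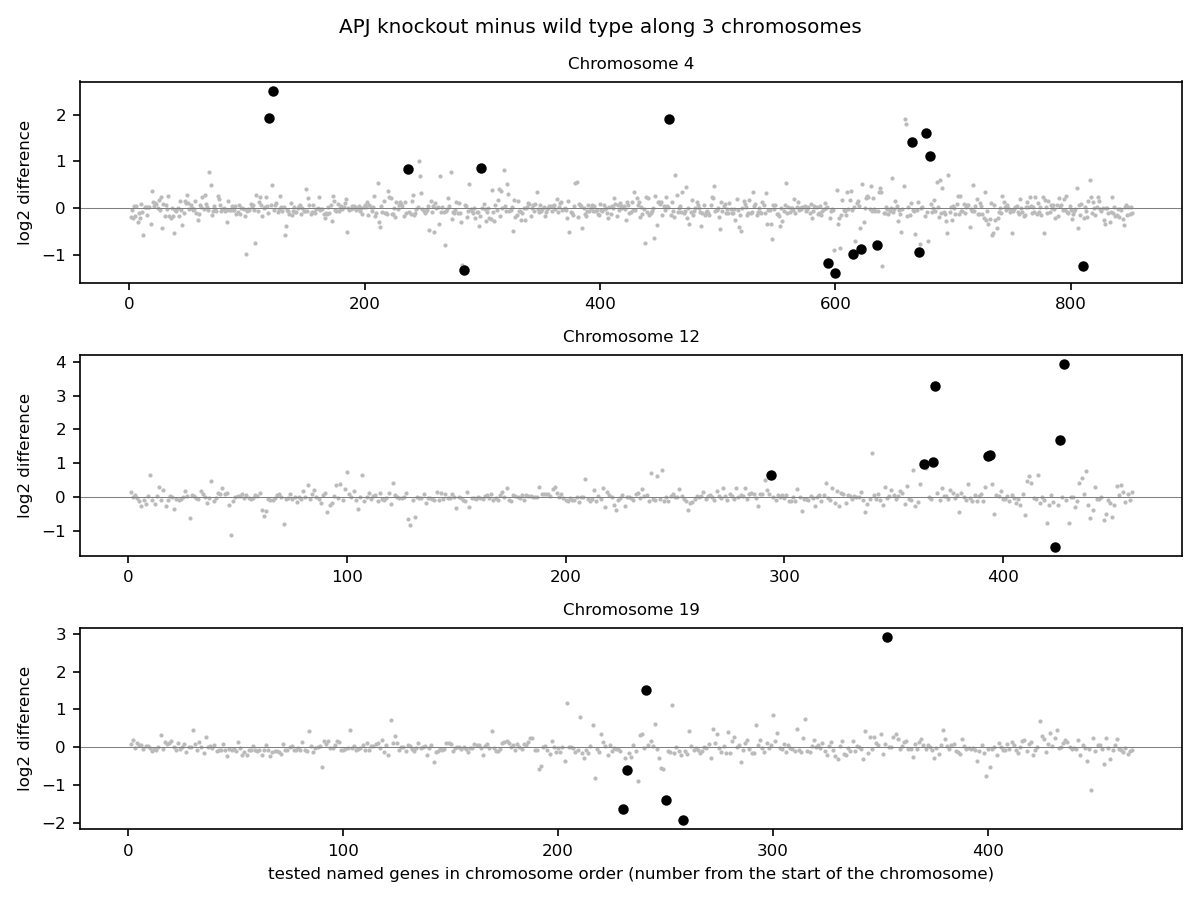
Log2 difference, APJ knockout minus wild type, of each tested named gene on chromosomes 4, 12 and 19 against its number in chromosome order, with called genes as black circles and all others in grey. The 16 called genes of chromosome 4, 9 of chromosome 12 and 6 of chromosome 19 include groups lying close together.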

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

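The fit to slide 1 alone and the normexp correction on median signals were chosen after seeing the data, and normexp on mean signals was not run. Counts below are higher and lower genes, against 89 and 45. They lay within 1.5 times under quantile normalisation (96 and 47), median scaling (117 and 47), normexp (116 and 65), the authors' table (84 and 41), the filter on all 6 arrays (63 and 37), the mean of probes (88 and 43) and the stricter threshold (64 and 31). Testing every probe gave 136 and 66, the intensity trend 129 and 69, trend with robust fitting 131 and 71, array weights 179 and 96, the slide block 184 and 101, and adjusted p 0.1 gave 182 and 90. Without the filter 49224 features were tested and 3 rose, 0 fell (limma), 0 of the 24 named genes passed, and Aplnr stayed at -1.69 (adjusted p = 0.186). The replicate block gave 4 and 1, 1 of the 24 named genes and Aplnr at -1.69 (adjusted p = 0.0791), and beyond these and the keratinocyte and platelet lists it ended no list call. Slide 1 alone gave 9 and 2, 5 of the 24 and Aplnr at -1.76 (adjusted p = 0.0853), with fewer samples. Leaving out 1 array gave 11 (without wild type replicate 2) to 45 higher, 1 (without wild type replicate 2) to 26 lower, 4 to 15 of the 24, and Aplnr from -1.84 to -1.57 (adjusted p = 0.0368 to 0.148). Of the 32 tested lists 8 passed, against 0 by camera with an estimated correlation, 4 by fry and 7 to 11 with 1 array left out. Slide 1 alone passed 6 and ended 2 calls, and the rank form of camera passed 7 and ended 1. The slide block passed 9 and array weights 10. Of the 8 main list calls, leaving out 1 array ended only the keratinocyte call (without wild type replicate 3 or APJ knockout replicate 3) and the platelet call (without APJ knockout replicate 1). Over all alternatives 3132 gene values kept their side of the threshold, 419 lost it and 49 gained it, and for lists these numbers were 665, 20 and 19, with no reversed call. The kept values include genes and lists that passed in neither fit, so they do not give the share of calls that held. The losses included 52 genes without the filter on dim probes and 51 with the replicate block. Some settings had fewer samples or tested more features, but the causes of these changes were not tested. Median differences over all genes stayed between -0.0428 and 0.00141. Weak signal limits Kif9, Loxl4, Hal, Fam155a and Sfrp1, which were not well above background in 1 group. It also limits Lrrc55 (1 of 3 knockout arrays well above background), Lyz2 and Pla2g5 (1 of 3 wild-type arrays), and Lrmda, Pax1, C1qa, C1qc and Krt15 (2 of 3).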

Other observations

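The tests of gene order and of single chromosomes, of tandem families, of segment gain or loss, of flanking sequence, of probe agreement and of the lymphatic list were chosen only after the results they concern were seen. For strain differences and for other epidermal genes the bounds were set before the test was run, but the patterns they concern had been seen. The following genes past the threshold were chosen after their values were seen. Ece1, the enzyme that activates endothelins, which lies in a segment of chromosome 4 with 3 other called genes, rose by 1.41 ± 0.12 and Ednrb, an endothelin receptor, by 1.19 ± 0.12 (SE, n = 3 per group, limma adjusted p = 0.0144 and 0.0206). Cysltr1, a receptor for cysteinyl leukotrienes, rose by 1.38, Cpm, a carboxypeptidase that trims peptides, by 1.42, and Rarres2, the chemoattractant chemerin, by 1.20. Meg3 and Mirg, maternally expressed imprinted RNAs that neighbour each other on chromosome 12, rose by 1.20 ± 0.16 and 1.24 ± 0.17. The transcription factor genes Zfhx3 (-0.81) and Klf8 (-0.77) fell. With the replicate number as a block these genes had adjusted p between 0.0649 and 0.14.

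Called genes lay closer together along the chromosomes than random draws of tested genes. Of 76 called genes with a position, 35 had another called gene within 20 tested genes, against a mean of 15.1 in 10000 random draws (permutation p = 2e-04). Chromosome 4 held 16 of 852 tested genes (Fisher's exact test, adjusted p = 0.000381) and chromosome 12 held 9 of 459 (adjusted p = 0.0119). Segments with at least 3 called genes numbered 6, with 23 genes, and 3 of them held both directions. On chromosome 19 Gcnt1, Pcsk5 (-0.61) and Kank1 were among the genes that fell and Gda (1.51) rose, and on chromosome 4 Map3k6 (-1.16), Trnp1, Cep85 (-0.97), Stmn1 (-0.87) and Clic4 (-0.78) all fell. Nearby on chromosome 4 Ece1, Pla2g5 (1.60, well above background on 1 of 3 wild-type arrays) and Nbl1 (1.11) rose and Pink1 (-0.94) fell. With the replicate number as a block none of the genes named in this paragraph so far passed. A530016L24Rik, in a chromosome 12 segment with Aspg, did (adjusted p = 0.0326).

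Shared signal within tandem families was argued against, since keeping 1 called gene per family left a permutation p of 0.002. Flanking sequence of the Aplnr allele cannot account for gathering on other chromosomes. With chromosome 2 left out, 33 of 72 called genes still had a called neighbour (permutation p = 2e-04). That result does not bear on Aplnr and Lrrc55, which neighbour each other on chromosome 2, where flanking sequence stays open. Gain or loss of whole segments was also argued against by a median log2 difference of -0.039 over all 108 tested genes of the 6 segments, although the Serpina segment alone had 0.926 over 6 genes. Strain differences in segments unlinked to Aplnr stay open as a candidate explanation: 27.1% of the 85 uncalled genes inside the segments had an unadjusted p under 0.05, against 7.98% of 13295 elsewhere (Fisher's exact p = 1.65e-07, odds ratio 4.28). Of called genes with more than 1 tested probe, 4 of 7 inside the segments (Gcnt1, Stmn1, Clic4 and Pla2g5) and 0 of 18 elsewhere had a probe that moved by less than 50% of the value used (Fisher's exact p = 0.00277), which sequence variants under probes could give. Shared regulation of neighbours after loss of APJ was not tested, and the labels give 1 strain for all samples.

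The rise of lymphatic markers was set against RNA from macrophages, whose markers rose too, and a larger share of lymphatic cells. Macrophage RNA was argued against as the whole cause, since the 10 members that macrophages do not express had a median difference of 0.448, with 9 above 0 and a median SE of 0.137. A larger share of lymphatic endothelial cells in the knockout sorts may account for the pattern: 1 of 6 restricted markers lay over 2 standard errors from their common mean of 0.424, in a range from 0.0778 to 0.85. Of the 14 members, 2 (Flt4 and Sox18) are also held by other lists. A change of expression within lymphatic cells after loss of APJ, which could pass the same test, stays open and was not tested.

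The fall of keratinocyte markers came mostly from wild type replicate 3, where the 14 members exceeded the other wild-type arrays by a median of 2.55, against -0.339 for the same replicate of the knockout. Krt5 exceeded them by 3.66 and Krt15 by 4.31, while Trp63, a transcription factor of basal epidermis, lay at -0.04. Epidermal cells in that sort may have added this RNA. Sorting was for endothelial cells but did not exclude all other signal: erythroid markers had a median log2 signal of 5.15 in wild type, beside 5.53 for pan-endothelial ones. Of 7 other epidermal genes 5 were higher in wild type replicate 3, with a median excess of 0.418. That lay between the bounds set before this test was run (at least 1 if epidermal cells were the cause, under 0.3 if not) and nearer the lower, so the test did not decide. An effect of APJ loss on these genes was not tested separately.

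With 3 arrays against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split called 89 higher and 45 lower genes, the largest count in 1 of the 10 splits for each direction, and the highest of the other splits called 0 by limma, with 267 to 4822 genes at an unadjusted p under 0.05. The real split had 1945 at that bound, fewer than 3 of the 9 others. For gene lists the real split gave 8 past the threshold and the highest other split 10, and 4 of the 10 splits, the real one included, gave at least as many. The split with 10 parted all 3 replicate pairs, as the real one does. For single lists, the lymphatic median of 0.489 exceeded the highest of the other splits, 0.276, the hypoxia median of 0.299 exceeded 0.158, and the fatty acid median of 0.173 exceeded 0.15. These lists still passed camera in other splits: the lymphatic list in 3 (lowest adjusted p 4.75e-05), the hypoxia list in 3 (3.06e-06) and the fatty acid list in 2 (0.000127), so a pass alone does not set the real split apart. The other lists past the threshold had a median that another split exceeded in size: 0.239 against 0.259 for sprouting, 0.454 against 1.12 for macrophages, 0.109 against 0.17 for the TGF-β and BMP response, 0.192 against 0.218 for platelets and 1.14 against 1.57 for keratinocytes. These 5 passed in 2 to 4 of the other splits.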
